A study of Mus musculus with 12 samples.

How the data were processed

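RNA from mouse uterus was sequenced in 12 libraries, 3 in each of 4 groups formed by the genotype and the horn that the labels give. The deposited files, 1 per library, hold raw counts per gene: whole numbers in a column that the header names as a count, for 54435 identifiers. The authors' processing notes name HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3, without a role for each, and state neither the genome build nor the annotation release. According to the labels, RNA was extracted with RNeasy kits and 1 µg of total RNA went into each library. Of the identifiers, 53801 were Ensembl genes, of which 53620 were matched to a symbol, and 634 were other identifiers that held 0.207% to 0.566% of the counts and stayed in the totals and the tests. Total counts lay between 15527781 and 18324380 per library.

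Libraries were grouped as the labels state, and none was left out of the main tests. Genes with low counts were removed with filterByExpr by group, which left 18286 genes. Scaling factors were computed by TMM, and quasi-likelihood tests were run with edgeR 4.0.16 in R 4.3.3 on a model with 1 mean per group over all 12 libraries. There were 5 comparisons: the surgical against the non-surgical horn in control and in knockout mice, knockout against control in the surgical and in the non-surgical horn, and the difference of the horn effect between genotypes (the interaction). P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Adjusted p-values of single genes are from edgeR, and those of gene lists are from limma. Piezo1 was also tested by an exact permutation of the 10 splits of 3 against 3 libraries, whose smallest two-sided p is 0.1.

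Gene lists were fixed before the data were examined: 37 lists of pathway genes and cell type markers, matched by symbol and then by synonym. Members measured, risen and fallen were counted with p-values adjusted over all genes and, separately, adjusted over the list alone. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, with an estimated correlation, and with fry. The genes named were set by a rule made before the data were examined. For each comparison of a pair of groups it took Piezo1 and the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 1, groups that did not overlap and a symbol that is not a predicted gene. For the interaction it took the 10 genes of each sign with the lowest p. For each list described it took up to 4 members with the lowest p, and for the decidual list always Prl8a2, Bmp2, Wnt4, Hand2 and Hoxa10. Genes with the largest share of counts in a library were named after their values were seen. The text prints part of the genes that the rule took.

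Where a group had no counts of a gene, the fold change is given as a lower bound with a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with a 95% counting interval. The procedure was tested on counts drawn from a negative binomial model with the spread and library sizes of these data. Means were those of the data, set to no difference in the comparison tested except for 200 genes with changes of known size. Genes were drawn independently. The rates that follow hold for that setting and do not cover comparisons in which most genes differ or 1 library shifts many genes together. At a 2-fold change 53% to 59% of changed genes were recovered in comparisons of a pair of groups and 23% in the interaction, at a 4-fold change 85% to 89% and 79%, and 4% to 7.4% of calls were false.

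Alternatives set before the data were examined were DESeq2 size factors, upper quartile scaling and total counts only; the DESeq2 1.42.0 test and limma-voom; no filter, and at least 10 counts in every library of a group; protein-coding genes only; a 2-fold minimum and an adjusted p under 0.01; only the 6 libraries compared; replicate numbers as a block; and leaving out each library in turn. Offsets for GC content and transcript length were added after the data were seen, as were the counts of every list without knockout surgical replicate 3. GENCODE M21 served only for gene type, GC content and length. All splits of the 6 libraries of each comparison into groups of 3, and 100 splits for the interaction, were run through the same test. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. An alternative planned for FPKM values was not run, since the files hold counts.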

Results

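Gene expression was measured by RNA sequencing in 12 libraries of mouse uterus after decidualization had been induced artificially on 1 side. The labels divide them into 4 groups of 3 libraries each: the non-surgical and the surgical side of the uterus (called horns here) in mice labelled WT (called control here) and in mice labelled PIEZO1 knockout. Piezo1 encodes a mechanically gated cation channel. The labels give uterus as the tissue and also name stromal cells, and the counts held markers of epithelium, smooth muscle, vessels and immune cells. Total counts per library ranged from 15527781 to 18324380, with group means of 17356395 in the control non-surgical, 17830775 in the control surgical, 15937532 in the knockout non-surgical and 16119445 in the knockout surgical libraries. After removal of genes with low counts, 18286 genes were tested. The labels do not say whether the libraries came from separate mice, so the p-values measure the spread between these libraries. Changes are given as log2 fold changes ± SE with 3 libraries per group, and counts scaled by library size (CPM of edgeR) as mean ± SD (n = 3). The labels and processing notes do not give the genome build, and gene positions are not printed here.

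The targeted gene, Piezo1 (ENSMUSG00000014444), was read in every library, with counts summed over the whole gene. In the non-surgical horn it was at 65.6, 81.4 and 44.7 CPM in the control libraries and at 22.2, 35.5 and 35.7 CPM in the knockout libraries. In the surgical horn it was at 39.2, 49.4 and 49.3 CPM in the control libraries and at 31.8, 28.6 and 62.2 CPM in knockout surgical replicates 1, 2 and 3. In the non-surgical horn the knockout value was 2.05-fold lower, at -1.04 ± 0.30 (edgeR unadjusted p = 0.00425, adjusted p = 0.378). The groups did not overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). With no filter on low counts this difference passed the threshold, at -1.07 (adjusted p = 0.0387). In the surgical horn the difference was -0.17 ± 0.30 (edgeR unadjusted p = 0.577, adjusted p = 0.730, exact two-sided permutation p = 0.6). Leaving out knockout surgical replicate 3 gave -0.60 (adjusted p = 0.130), and leaving out knockout surgical replicate 2 gave 0.03. Between horns, Piezo1 differed by -0.48 ± 0.29 in control (adjusted p = 0.175, exact two-sided permutation p = 0.3) and by 0.39 ± 0.30 in knockout mice (adjusted p = 0.278, exact two-sided permutation p = 0.6). Scaling by total counts only gave -1.01 in control, which passed the threshold, and -0.03 in knockout mice. The difference between these horn effects was 0.87 ± 0.42 (adjusted p = 0.208).

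**Figure D1:**
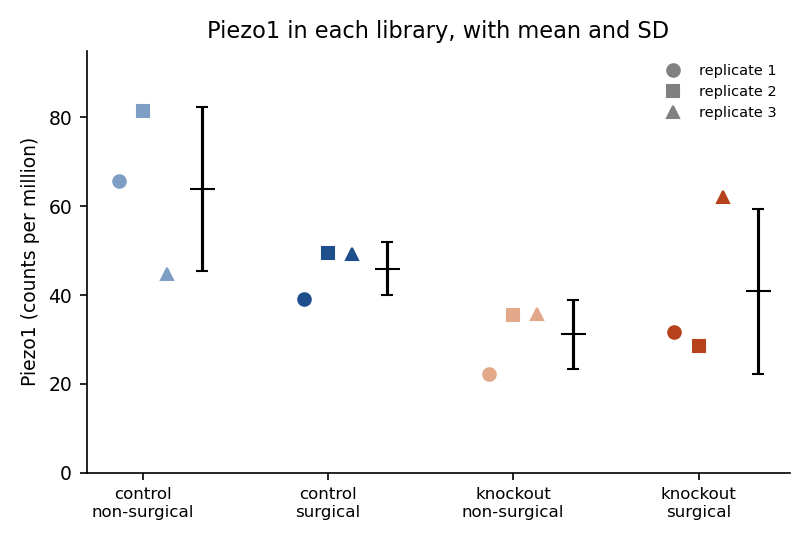
Piezo1 in CPM (vertical axis) in each of the 12 libraries by group (horizontal axis), with symbols for replicate numbers and bars for the mean and SD (n = 3). Knockout surgical replicate 3, at 62.2, lies above the 3 control surgical libraries.

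The libraries separated first by horn. The first principal component held 84.2% of the variance and parted all surgical from all non-surgical libraries. The second held 5.61% and parted the control from the knockout surgical libraries. Knockout surgical replicate 3 stood apart from its group: its mean correlation with the other knockout surgical libraries was 0.949, against 0.988 between those libraries, and 0.884 with the control surgical libraries. Desmin (Des), an intermediate filament gene of muscle and decidua, took the largest share of its counts, while Gpx3, a secreted glutathione peroxidase, did so in the other surgical libraries and Eef1a1, a translation factor, in the non-surgical ones. The 10 most abundant genes took a mean of 5.09% of counts in the control non-surgical, 9.86% in the control surgical, 5.33% in the knockout non-surgical and 7.15% in the knockout surgical libraries.

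**Figure D2:**
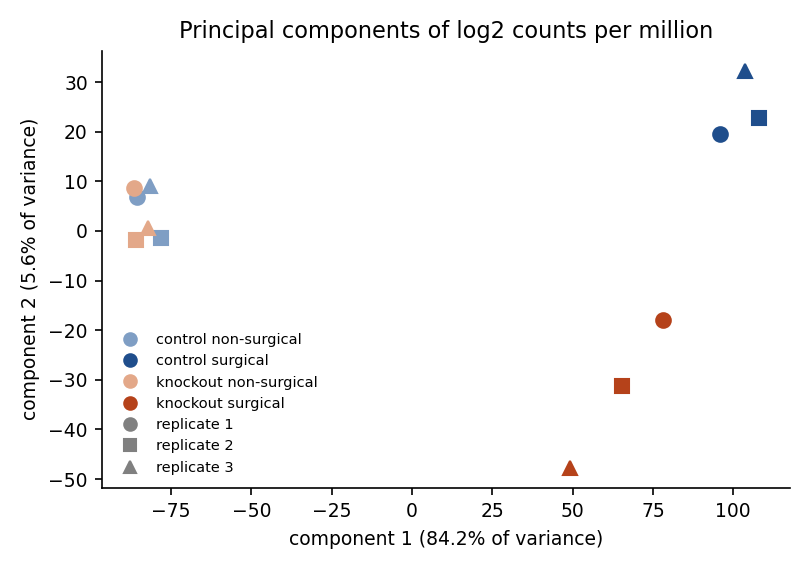
Principal component 1 (84.2% of variance) against component 2 (5.61%) of log2 CPM of the most variable genes for the 12 libraries, colored by group, with symbols for replicate numbers. Surgical and non-surgical libraries part along component 1, where knockout surgical replicate 3 lies at 49.3 and the other surgical libraries between 65.4 and 107.9.

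The comparison of the horns in control mice shows which genes differed after artificial decidualization. Prl8a2 (ENSMUSG00000018259), a prolactin-family hormone of the decidua, had 1 count over the 3 control non-surgical libraries and 11650 ± 3537 CPM in the surgical ones, a ratio of 710700 (95% counting interval 127600 to 28070000). Bmp2, a growth factor needed for decidualization, rose by 7.06 ± 0.58 (adjusted p = 6.53e-07) to 629 ± 127 CPM. Wnt4, a signal that acts downstream of Bmp2, rose by 5.02 ± 0.36 (adjusted p = 2.26e-07), and Hand2, a progesterone-dependent transcription factor of the stroma, by 4.07 ± 0.31 (adjusted p = 3.42e-07). Cyp11a1, which starts steroid synthesis from cholesterol, rose by 12.83 ± 0.61 to 1242 ± 219 CPM, and by 13.47 without control non-surgical replicate 2. Epithelial genes fell, among them the cadherin gene Cdh16 (-8.32 ± 0.55, and -9.43 without control surgical replicate 1) and Epcam (-3.25 ± 0.29), while Des rose by 3.40 ± 0.17 to 6757 ± 1192 CPM.

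Among the decidual stroma markers, 25 of 28 measured genes rose, 1 fell and 2 did not pass the test (camera adjusted p = 5.21e-09, adjusted p = 0.209 with an estimated correlation). Counts adjusted over the list alone were the same here and are given elsewhere only where they differ. Hoxa10, a homeobox gene of the stroma, rose by 0.37 ± 0.15 (adjusted p = 0.0459), a call that turned to -0.17 with total counts only. It also ended without any 1 of the 6 control libraries (0.25 without control non-surgical replicate 1 and from 0.35 to 0.41 without the others), and without knockout non-surgical replicate 1 or 3 or knockout surgical replicate 2 (from 0.36 to 0.37). All 8 measured members of the prolactin family rose (adjusted p = 1.96e-04, adjusted p = 0.209 with an estimated correlation). Prl3c1 and Prl8a9 had no counts in the control non-surgical libraries and were at least 7090-fold and 3880-fold higher in the surgical ones, taking 3 counts over the group as the floor. Reads of prolactin-family genes may be shared with near-identical copies, and intervals and floors cover counting error only. Other large rises included Erv3, an endogenous retroviral gene with 1 count against 1331 ± 693 CPM (ratio 80860, 95% counting interval 14510 to 3194000), and Hephl1, a copper oxidase gene, at least 5803-fold higher.

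Cell cycle genes rose in 24 of 25 cases (adjusted p = 9.69e-10, adjusted p = 0.532 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 up by 10.06 ± 0.49 and the proliferation marker Mki67 by 3.10 ± 0.22. Of 18 polyploidy and endocycle genes, 13 rose and 2 fell (adjusted p = 0.00170, adjusted p = 0.234 with an estimated correlation), with E2f8, a regulator of endocycles, up by 5.75 ± 0.40 and the cell cycle inhibitor Cdkn1a by 3.79 ± 0.19. Cholesterol and steroid synthesis genes rose in 16 of 18 cases and none fell (adjusted p = 3.18e-07, adjusted p = 0.157 with an estimated correlation), including the receptor gene Ldlr (3.30 ± 0.20). Of 21 glycolysis and hypoxia genes, 16 rose and 3 fell (adjusted p = 1.96e-04, adjusted p = 0.601 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 4.14 ± 0.23. Endoplasmic reticulum stress genes rose in 16 of 18 cases and none fell (adjusted p = 1.13e-06, adjusted p = 0.279 with an estimated correlation). Manf, a secreted protein gene of this stress response, rose by 2.30 ± 0.17. Ribosomal protein genes fell in 38 of 77 cases and 3 rose (37 and 3 adjusted over the list alone; adjusted p = 7.04e-04, adjusted p = 0.813 with an estimated correlation), with Rpl9 down at -0.58 ± 0.11, and their reads may be shared with pseudogenes.

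Markers of other cell types moved beside these groups. Luminal epithelium markers fell in 16 of 19 cases and none rose (17 fell adjusted over the list alone; adjusted p = 7.19e-06, adjusted p = 0.532 with an estimated correlation). Smooth muscle markers fell in 14 of 17 cases and 1, Des, rose (adjusted p = 0.00269, adjusted p = 0.716 with an estimated correlation). The myosin kinase gene Mylk fell, at -2.38 ± 0.30. Endothelial markers rose in 12 of 17 cases and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.00189, adjusted p = 0.633 with an estimated correlation). The junction gene Pecam1 rose by 1.35 ± 0.14. Focal adhesion and actin genes rose in 15 of 24 cases and 1 fell (adjusted p = 0.00189, adjusted p = 0.633 with an estimated correlation). The integrin gene Itga5 rose by 2.55 ± 0.21. All 5 measured red blood cell markers rose (adjusted p = 0.0477, adjusted p = 0.685 with an estimated correlation), and this list lost its camera call without control non-surgical replicate 1 or 3, control surgical replicate 2 or 3, or knockout surgical replicate 3 (adjusted p from 0.0512 to 0.0634). Among 19 uterine natural killer cell markers 8 rose and 7 fell, with no camera call (adjusted p = 0.675). The granule genes Gzma, Gzmd and Gzme rose by 4.76 ± 0.48, 9.60 ± 0.76 and 9.97 ± 0.95, and granzyme reads may be shared between near-identical copies. Without control non-surgical replicate 1 Gzmd and Gzme rose by 10.36 and 12.08, and without replicate 2 of that group Gzme rose by 9.35. The median of this list was 0.10, and it turned to -0.11 with upper quartile scaling and to -0.42 with total counts only.

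Lists without a camera call also held genes that passed. Of all 18286 genes tested, 5625 rose and 6041 fell in this comparison, so counts near these shares do not set a list apart. Glandular epithelium markers fell in 9 of 14 cases and 2 rose (3 rose adjusted over the list alone). The secreted factor gene Cxcl15 fell, at -8.35 ± 0.51. Of 20 progesterone signalling genes 10 fell and 4 rose (5 rose adjusted over the list alone), with the hedgehog targets Ptch1 and Gli1 down at -4.12 ± 0.19 and -4.66 ± 0.25. Estrogen-responsive genes fell in 9 of 16 cases and 3 rose. Muc1 fell, at -3.80 ± 0.41. YAP and TAZ target genes rose in 14 of 23 cases and 8 fell. Dock5 rose by 3.86 ± 0.22. Mechanosensitive ion channel genes fell in 8 of 16 cases and 2 rose. The potassium channel gene Kcnk2 rose by 4.06 ± 0.30. For extracellular matrix genes 13 of 28 rose and 6 fell, for matrix-degrading enzymes and inhibitors 9 of 21 rose and 7 fell, and for BMP and TGF-beta genes 10 of 26 rose and 10 fell (11 rose adjusted over the list alone). The medians of these 3 lists, of the 28 calcium signalling genes (12 rose, 10 fell), of the 27 Wnt pathway genes (13 rose, 12 fell), of the 8 neutrophil markers (3 rose, 2 fell; 3 and 1 adjusted over the list alone) and of the 13 mitochondrially encoded genes (4 rose; 1 adjusted over the list alone) were positive and turned negative with total counts only, as did those of the BMP and TGF-beta and the calcium signalling genes with upper quartile scaling. Serpine1, the main inhibitor of plasminogen activators, rose by 6.74 ± 0.24. Angiogenic factors rose in 8 of 16 cases and 4 fell, immediate early genes rose in 7 of 15 and 3 fell, macrophage markers rose in 3 of 15 and 7 fell (8 fell adjusted over the list alone), interferon-stimulated genes rose in 5 of 22 and 7 fell, and inflammatory cytokines and chemokines rose in 1 of 15 and 5 fell (0 and 5 adjusted over the list alone).

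By the edgeR test 11666 of 18286 genes passed in control mice, 5625 higher and 6041 lower in the surgical horn, and 7266 of them changed at least 2-fold. The balance depended on the scaling: 4444 were higher and 7488 lower with upper quartile scaling, and 3135 higher and 9757 lower with total counts only, which shifted the median of all genes to -0.60.

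In knockout mice the same comparison gave the horn difference under the knockout genotype. Prl8a2 had no counts in the knockout non-surgical libraries and 3250 ± 810 CPM in the surgical ones, at least 60940-fold higher. Bmp2 rose by 5.62 ± 0.55 (adjusted p = 3.97e-06), Wnt4 by 4.01 ± 0.34 (adjusted p = 1.28e-06), Hand2 by 3.13 ± 0.29 (adjusted p = 2.87e-06) and Hoxa10 by 0.59 ± 0.15 (adjusted p = 0.00452). Cyp11a1 rose by 12.26 ± 0.60, the alkaline phosphatase gene Alpl by 6.95 ± 0.31 and Serpine1 by 7.15 ± 0.25. Lox, which cross-links collagen and elastin, rose by 4.77 ± 0.33 (adjusted p = 3.02e-07). Ereg, a growth factor of the EGF family, had no counts in the non-surgical libraries and was at least 2674-fold higher. Without knockout surgical replicate 3 this bound was 333.3-fold. The epithelial signal gene Ihh and the vitamin C synthesis gene Gulo fell, at -5.58 ± 0.42 (-6.39 without knockout surgical replicate 2) and -5.98 ± 0.39.

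Decidual stroma markers rose in 25 of 28 cases and none fell (adjusted p = 2.92e-10, adjusted p = 0.164 with an estimated correlation), and all 8 prolactin-family genes rose (adjusted p = 5.25e-05, adjusted p = 0.164 with an estimated correlation). Cell cycle genes rose in 23 of 25 cases (adjusted p = 4.35e-08, adjusted p = 0.415 with an estimated correlation). Rrm2 rose by 8.07 ± 0.46. Of 18 polyploidy and endocycle genes 14 rose and 2 fell (adjusted p = 5.69e-04, adjusted p = 0.175 with an estimated correlation). E2f8 rose by 5.34 ± 0.39. All 18 cholesterol and steroid synthesis genes rose (adjusted p = 2.47e-07, adjusted p = 0.164 with an estimated correlation). Ldlr rose by 2.78 ± 0.20. Glycolysis and hypoxia genes rose in 18 of 21 cases and 1 fell (adjusted p = 3.98e-07, adjusted p = 0.324 with an estimated correlation). Slc2a1 rose by 5.21 ± 0.25. Endoplasmic reticulum stress genes rose in 16 of 18 cases (adjusted p = 3.06e-07, adjusted p = 0.211 with an estimated correlation). Hspa5 rose by 2.11 ± 0.18. Ribosomal protein genes fell in 61 of 77 cases and 1 rose (adjusted p = 1.78e-11, adjusted p = 0.419 with an estimated correlation). Rpl22 fell, at -0.85 ± 0.11.

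Extracellular matrix genes rose in 23 of 28 cases and 1 fell (adjusted p = 2.47e-07, adjusted p = 0.419 with an estimated correlation). Col4a1 rose by 3.14 ± 0.26. Matrix-degrading enzymes and inhibitors rose in 15 of 21 cases and none fell (16 rose adjusted over the list alone; adjusted p = 1.29e-04, adjusted p = 0.419 with an estimated correlation). Focal adhesion and actin genes rose in 22 of 24 cases (adjusted p = 4.35e-08, adjusted p = 0.248 with an estimated correlation). Itga5 rose by 3.56 ± 0.21. YAP and TAZ target genes rose in 15 of 23 cases and none fell (15 and 1 adjusted over the list alone; adjusted p = 6.45e-05, adjusted p = 0.175 with an estimated correlation). Dock5 rose by 3.16 ± 0.21. Immediate early genes rose in 12 of 15 cases (adjusted p = 6.55e-04, adjusted p = 0.476 with an estimated correlation). Klf4 rose by 1.81 ± 0.20. BMP and TGF-beta genes rose in 15 of 26 cases and 5 fell (adjusted p = 0.0262, adjusted p = 0.378 with an estimated correlation). Smad7 rose by 2.62 ± 0.23. Endothelial markers rose in 15 of 17 cases (adjusted p = 5.25e-05, adjusted p = 0.386 with an estimated correlation), and angiogenic factors rose in 11 of 16 and 4 fell (adjusted p = 0.00962, adjusted p = 0.398 with an estimated correlation). Angpt2 rose by 4.40 ± 0.41.

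Luminal epithelium markers fell in 14 of 19 cases and 1 rose (adjusted p = 7.29e-05, adjusted p = 0.398 with an estimated correlation). The tight junction gene Cldn3 fell, at -3.04 ± 0.21. Of 17 smooth muscle markers 3 rose and 3 fell, with no camera call (adjusted p = 0.808), while without knockout surgical replicate 3 2 rose and 7 fell (adjusted p = 0.0734). Des rose by 4.03 ± 0.18. Macrophage markers rose in 9 of 15 cases (adjusted p = 0.00788, adjusted p = 0.526 with an estimated correlation) and in 6 without knockout surgical replicate 3, where the camera call ended (adjusted p = 0.0684). The receptor gene Csf1r rose by 3.71 ± 0.27. Neutrophil markers rose in 6 of 8 cases (adjusted p = 0.0430, adjusted p = 0.419 with an estimated correlation), a camera call that ended without knockout surgical replicate 3 (0.0576) and without knockout non-surgical replicate 1 (0.0549) or 2 (0.0654). Inflammatory cytokines and chemokines rose in 8 of 15 cases and 2 fell, and without knockout surgical replicate 3 both counts were 3. Uterine natural killer cell markers fell in 10 of 19 cases and 5 rose, with no camera call (adjusted p = 0.0886), and Ncr1, an activating receptor gene of these cells, fell (-3.30 ± 0.40). All 5 red blood cell markers rose, with no camera call (adjusted p = 0.0549). Glandular epithelium markers fell in 8 of 14 cases and 5 rose, progesterone signalling genes fell in 8 of 20 and 6 rose, and estrogen-responsive genes fell in 4 of 16 and 3 rose (4 and 2 adjusted over the list alone; 7 and 2 without knockout surgical replicate 3). Without that library 3 genes fell in each of the extracellular matrix, glycolysis and hypoxia, and YAP and TAZ lists, 2 among matrix-degrading enzymes and inhibitors, and 1 in each of the focal adhesion and actin and the immediate early lists, and 2 mitochondrially encoded genes rose. Calcium signalling genes rose in 15 of 28 cases and 6 fell, and with total counts only 8 rose and 10 fell. Mechanosensitive ion channel genes rose in 4 of 16 cases and 4 fell (3 and 4 adjusted over the list alone), and their median turned from 0.11 to -0.11 with upper quartile scaling and to -0.31 with total counts only. Wnt pathway genes rose in 10 of 27 and 13 fell, interferon-stimulated genes rose in 2 of 22 and 8 fell, and none of 13 mitochondrially encoded genes passed (median 0.00, and -0.42 with total counts only, where 7 fell).

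By the edgeR test 10528 genes passed in knockout mice, 5377 higher and 5151 lower in the surgical horn, and 6063 of them changed at least 2-fold. With upper quartile scaling 4121 were higher and 6716 lower, and with total counts only, which shifted the median of all genes to -0.44, 3209 were higher and 8411 lower.

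**Figure D3:**
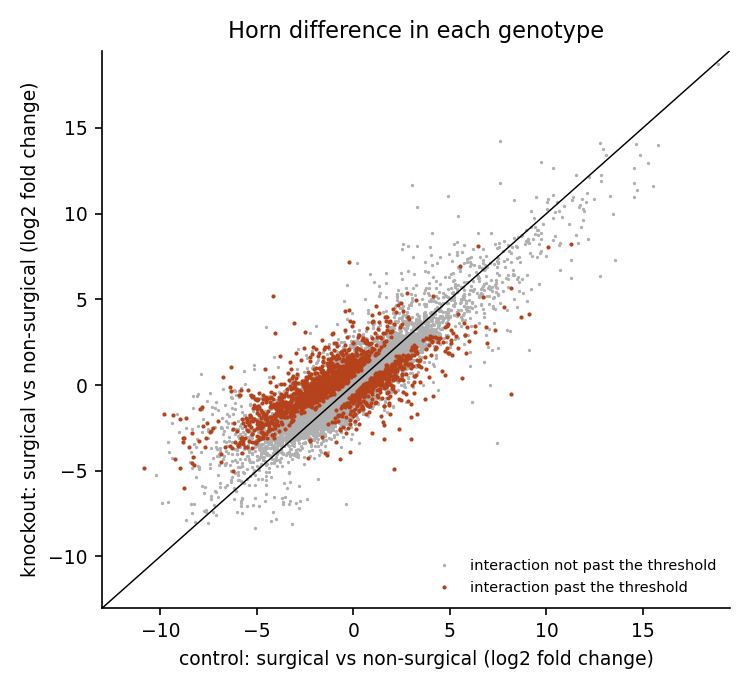
Log2 fold change between the surgical and the non-surgical horn in control (horizontal axis) and in knockout mice (vertical axis) for 18286 genes, with 1623 genes past the threshold of the interaction test in color and a line of equal change. The effects correlated at r = 0.881 over the 14502 genes with an average log2 CPM of at least 1.

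The comparison of knockout with control in the surgical horn follows the genotype labels, since the Piezo1 counts did not differ past the threshold there. Genes of uterine natural killer cells were lower in the knockout: Gzma, a granule protease gene, fell from 33.2 ± 10.2 to 1.56 ± 1.22 CPM (-4.41 ± 0.48, adjusted p = 3.03e-04, and -5.22 without knockout surgical replicate 1), and Il2rb, a receptor subunit for interleukins that sustain these cells, fell from 55.7 ± 16.6 to 7.81 ± 1.88 CPM (-2.83 ± 0.27, adjusted p = 2.22e-04). Of 8 prolactin-family genes 3 were lower, with Prl8a2 at -1.84 ± 0.27 (adjusted p = 0.00153) and Prl3c1, at 346 ± 32.3 against 22.9 ± 14.6 CPM, at -3.92 ± 0.49 (adjusted p = 0.00144). Genes of luminal epithelium, smooth muscle and extracellular matrix were higher, among them Epcam (2.75 ± 0.28, adjusted p = 2.51e-04), Mylk (1.44 ± 0.29, adjusted p = 0.00471) and Loxl1, a matrix cross-linking enzyme gene (2.05 ± 0.35, adjusted p = 0.00209). Mmp11, a matrix metalloproteinase gene, rose from 12.2 ± 0.456 to 60.3 ± 27.9 CPM (2.30 ± 0.25, adjusted p = 3.14e-04).

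Uterine natural killer cell markers fell in 14 of 19 cases and none rose (adjusted p = 7.63e-12, adjusted p = 0.459 with an estimated correlation), and 14 also fell without knockout surgical replicate 3. Gzmd, Gzme and Gzmf fell, at -3.94 ± 0.53, -4.12 ± 0.62 and -3.80 ± 0.44, and without knockout surgical replicate 1 these became -4.97, -5.57 and -4.57, with Gzma at -5.22. The interleukin 15 receptor gene Il15ra fell (-1.56 ± 0.16). Il15ra and Il15 are members of this list but were left out of the later test over markers of these cells. Among 28 decidual stroma markers 7 fell, 5 rose and 16 did not pass (8 and 6 adjusted over the list alone; adjusted p = 0.0227, adjusted p = 0.483 with an estimated correlation); the median moved from -0.22 to -0.11 with total counts only, where 6 fell and 6 rose. This camera call ended without knockout surgical replicate 3 (adjusted p = 0.0575) and without control surgical replicate 2 (0.0537). Hand2 fell (-1.02 ± 0.27, adjusted p = 0.0191), a call that ended without control surgical replicate 2 (-0.95, adjusted p = 0.0662) or 3 (-0.95, adjusted p = 0.0672). Bmp2 fell (-1.40 ± 0.44, adjusted p = 0.0405), which ended without any 1 of the 3 control surgical libraries (-1.55, -1.27 and -1.36) and without any 1 of the 6 non-surgical libraries, where the value stayed at -1.39. Wnt4 was at -0.19 ± 0.30 (adjusted p = 0.695) and Hoxa10 at -0.04 ± 0.15 (adjusted p = 0.889), and both were above 0 without knockout surgical replicate 3, at 0.11 and 0.09. Hoxa10 was also above 0 with total counts only, at 0.07. In the prolactin family 3 of 8 genes fell and 5 did not pass, with no camera call (adjusted p = 0.196). Other large falls were those of Acsbg1, a fatty acid activating enzyme gene (-4.27 ± 0.40), and Chl1, a cell adhesion gene (-4.35 ± 0.48, and -5.06 without knockout surgical replicate 1).

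Luminal epithelium markers rose in 17 of 19 cases and 1 fell, with the same counts without knockout surgical replicate 3 (adjusted p = 2.15e-08, adjusted p = 0.459 with an estimated correlation). The keratin gene Krt7 rose by 3.03 ± 0.40 (2.32 without knockout surgical replicate 3) and Wnt7a, a signal of the luminal epithelium, by 2.82 ± 0.42. Smooth muscle markers rose in 16 of 17 cases (17 adjusted over the list alone; adjusted p = 1.57e-08, adjusted p = 0.470 with an estimated correlation) and in 11 without knockout surgical replicate 3. Oxtr, the oxytocin receptor gene, rose by 4.54 ± 0.74, and by 2.96 without that library. Glandular epithelium markers rose in 3 of 14 cases, with no camera call (adjusted p = 0.189), and Cxcl15 rose by 4.08 ± 0.65. Estrogen-responsive genes rose in 10 of 16 cases and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00434, adjusted p = 0.459 with an estimated correlation). The secreted lactoferrin gene Ltf rose by 4.69 ± 0.70 (3.72 without knockout surgical replicate 2). Progesterone signalling genes rose in 5 of 20 cases and 2 fell (6 and 2 adjusted over the list alone), with no camera call (adjusted p = 0.623), with 2 and 2 without knockout surgical replicate 3 and 3 and 3 with offsets for GC content and transcript length. Clca1, a secreted regulator of chloride channels, rose by 5.85 ± 0.71 and, without control surgical replicate 1, by 7.83. Calb1, a calcium-binding protein gene of the epithelium, rose by 6.38 ± 1.41, and by 3.98 without knockout surgical replicate 2 or 7.07 without control surgical replicate 3.

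Extracellular matrix genes rose in 20 of 28 cases and none fell (23 rose adjusted over the list alone; adjusted p = 7.68e-09, adjusted p = 0.470 with an estimated correlation), and without knockout surgical replicate 3 13 rose and 1 fell. The collagen gene Col6a2 rose by 1.81 ± 0.33, and Thbs1, a matrix glycoprotein gene, by 2.70 ± 0.45 (1.84 without that library). Matrix-degrading enzymes and inhibitors rose in 14 of 21 cases and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 1.18e-05, adjusted p = 0.470 with an estimated correlation), with Mmp2 up by 1.69 ± 0.25 and the plasminogen activator gene Plat by 2.05 ± 0.30 (1.47 without knockout surgical replicate 3). The largest rises, Mmp10 (8.62 ± 1.60) and Mmp13 (7.95 ± 1.74), were 4.79 and 3.32 without knockout surgical replicate 3. Mmp3 rose by 5.48 ± 1.26, by 2.67 without that library and by 6.61 without control surgical replicate 1. YAP and TAZ target genes rose in 11 of 23 cases and 3 fell (12 and 4 adjusted over the list alone; adjusted p = 0.00725, adjusted p = 0.459 with an estimated correlation). The receptor gene Axl rose by 0.99 ± 0.19. Focal adhesion and actin genes rose in 8 of 24 cases and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00321, adjusted p = 0.470 with an estimated correlation), and in 4 without knockout surgical replicate 3. The actinin gene Actn1 rose by 0.89 ± 0.16. Calcium signalling genes rose in 14 of 28 cases and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 0.00807, adjusted p = 0.459 with an estimated correlation), and without that library 8 rose and 1 fell. Rcan2, a calcineurin regulator gene, rose by 2.60 ± 0.30. BMP and TGF-beta genes rose in 10 of 26 cases and 4 fell (14 and 4 adjusted over the list alone; adjusted p = 0.0147, adjusted p = 0.459 with an estimated correlation), a camera call that ended without knockout surgical replicate 3 (adjusted p = 0.0575). Tgfb3 rose by 0.92 ± 0.16.

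Mechanosensitive ion channel genes, the list that holds Piezo1, rose in 5 of 16 cases and 1 fell (6 and 1 adjusted over the list alone), with no camera call (adjusted p = 0.0835), and without knockout surgical replicate 3 1 rose and 1 fell. The cation channel gene Trpc3 rose by 1.92 ± 0.38. Piezo2, the related channel gene, rose by 0.84 ± 0.23 (adjusted p = 0.0218), a call that ended without knockout surgical replicate 3 (0.59, adjusted p = 0.0820) and without control surgical replicate 1 (0.74, adjusted p = 0.0756) or 3 (0.81, adjusted p = 0.0765). Wnt pathway genes rose in 8 of 27 cases and 3 fell, with no camera call (adjusted p = 0.189). Nkd2, an inhibitor of the pathway, rose by 2.58 ± 0.23 and Wnt5a fell (-1.33 ± 0.14). Angiogenic factors rose in 7 of 16 cases and 2 fell (6 and 1 without knockout surgical replicate 3), with no camera call (adjusted p = 0.0770), and Angpt1 rose by 1.26 ± 0.22. Endothelial markers rose in 4 of 17 cases (6 rose and 1 fell adjusted over the list alone), with no camera call (adjusted p = 0.114), and in 2 without knockout surgical replicate 3. Vwf rose by 1.03 ± 0.24.

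Macrophage markers rose in 8 of 15 cases (9 adjusted over the list alone; adjusted p = 0.00434, adjusted p = 0.50 with an estimated correlation) and in 3 without knockout surgical replicate 3, and the lysozyme gene Lyz2 rose by 1.34 ± 0.26. Inflammatory cytokines and chemokines rose in 8 of 15 cases (9 adjusted over the list alone; adjusted p = 0.00434, adjusted p = 0.483 with an estimated correlation) and in 1 without that library. The cytokine genes Il1b and Tnf rose by 4.96 ± 1.24 and 4.21 ± 1.04. Without knockout surgical replicate 3 they were at 1.03 and 1.57 and did not pass, nor did they without any 1 of the 3 control surgical libraries (from 4.90 to 5.05 and from 3.99 to 4.37). Neutrophil markers rose in 4 of 8 cases (5 adjusted over the list alone; adjusted p = 0.0358, adjusted p = 0.470 with an estimated correlation), a camera call that ended without control surgical replicate 1 (adjusted p = 0.0750). The receptor gene Csf3r rose by 2.76 ± 0.62, and by 1.40 without knockout surgical replicate 3. Red blood cell markers fell in 3 of 5 cases (5 adjusted over the list alone; adjusted p = 0.00807, adjusted p = 0.470 with an estimated correlation). The hemoglobin gene Hbb-bt fell (-1.21 ± 0.34), a call that ended without control surgical replicate 2 (-1.09) or 3 (-0.92) or knockout surgical replicate 1 (-1.10), and its reads may be shared with the other beta-globin gene.

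Cholesterol and steroid synthesis genes fell in 3 of 18 cases (2 adjusted over the list alone; adjusted p = 0.00235, adjusted p = 0.459 with an estimated correlation). The lanosterol synthase gene Lss fell, at -2.55 ± 0.28. Endoplasmic reticulum stress genes fell in 3 of 18 cases (6 adjusted over the list alone; adjusted p = 0.00434, adjusted p = 0.470 with an estimated correlation). Asns fell, at -0.64 ± 0.12. Interferon-stimulated genes fell in 3 of 22 cases (2 adjusted over the list alone; adjusted p = 0.0211, adjusted p = 0.568 with an estimated correlation), a camera call that ended without control surgical replicate 3 (0.0877) or knockout surgical replicate 2 (0.0584). Isg15 fell (-1.11 ± 0.26). Glycolysis and hypoxia genes rose in 5 of 21 cases (6 adjusted over the list alone; adjusted p = 0.0207, adjusted p = 0.536 with an estimated correlation) and immediate early genes in 4 of 15 (5 adjusted over the list alone; adjusted p = 0.0204, adjusted p = 0.568 with an estimated correlation). The first of these calls ended without knockout surgical replicate 3 (0.0658) or control surgical replicate 3 (0.0873), and the other without knockout surgical replicate 3 (0.373). Pfkfb3, a regulator of glycolysis, rose by 2.12 ± 0.50 (0.89 without knockout surgical replicate 3), and the nuclear receptor gene Nr4a1 by 1.64 ± 0.39 (0.82 without it). Of 25 cell cycle genes 1, Rrm2, fell (0 adjusted over the list alone; adjusted p = 0.0379, adjusted p = 0.631 with an estimated correlation). The camera call ended without knockout surgical replicate 3 (0.776) or control surgical replicate 1 (0.284), and the call of Rrm2 (-1.18 ± 0.33) without control surgical replicate 2 (-1.11) or 3 (-1.14). Polyploidy and endocycle genes rose in 1 of 18 cases (0 without knockout surgical replicate 3) and fell in 1, Mdm2 (-0.93 ± 0.14), with no camera call (adjusted p = 0.276) and a median of -0.10 that turned to 0.00 with total counts only. The median of 77 ribosomal protein genes was -0.16, with 1 gene higher (0 adjusted over the list alone; adjusted p = 8.57e-04, adjusted p = 0.568 with an estimated correlation). In this list 1 rose and 7 fell with offsets for GC content and transcript length, 1 and 6 with the DESeq2 test, 1 and 1 with DESeq2 size factors, and 0 and 0 without knockout surgical replicate 3. None of 13 mitochondrially encoded genes passed.

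By the edgeR test 3966 genes passed in the surgical horn, 2470 higher and 1496 lower in the knockout, and 2111 of them differed at least 2-fold. The count was 2611 without knockout surgical replicate 3, 2307 without control surgical replicate 2 and 2187 without control surgical replicate 3; the higher and lower counts were 3045 and 988 with total counts only and 2096 and 2702 with offsets for GC content and transcript length.

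**Figure D4:**
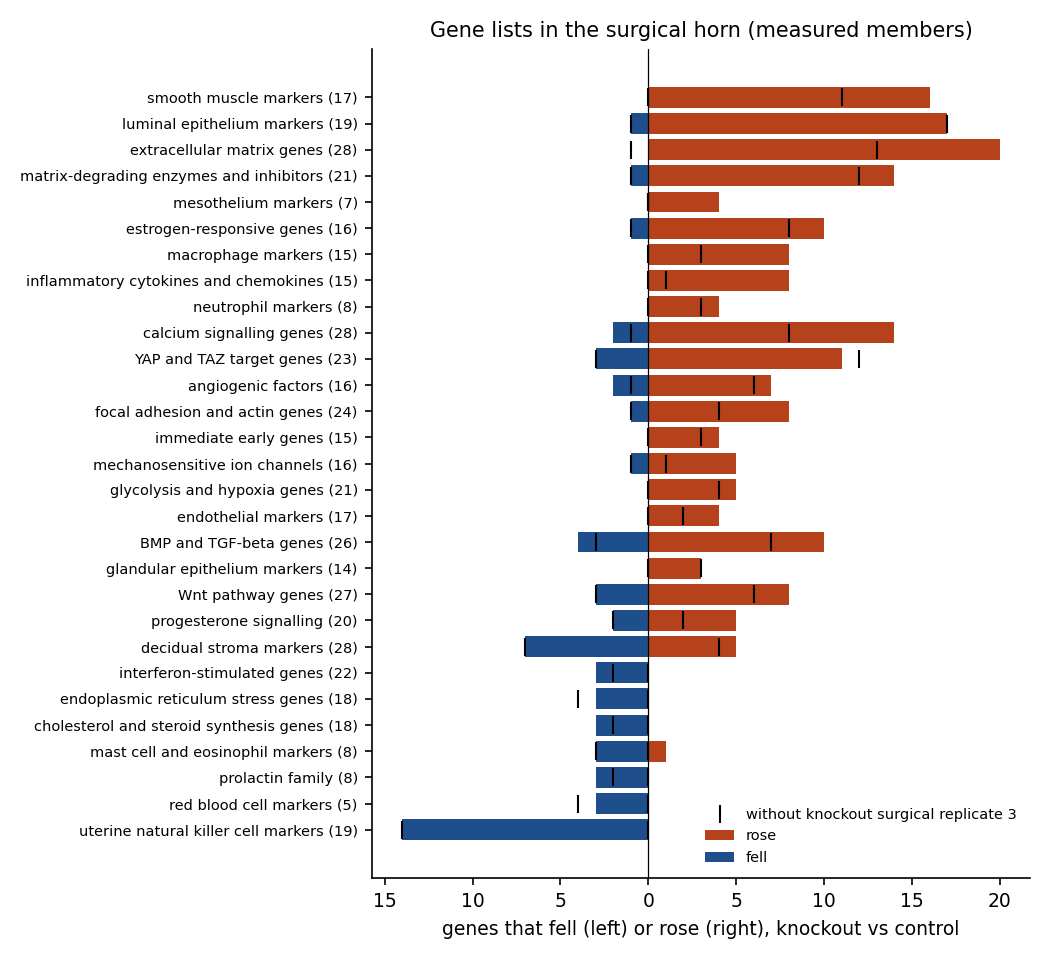
Number of genes of each list that fell (left) or rose (right) in knockout against control surgical libraries (horizontal axis), for lists with at least 3 genes past the threshold (vertical axis, measured members in parentheses), with ticks for the counts without knockout surgical replicate 3. Natural killer cell markers (14 fell) and luminal epithelium markers (17 rose) had the same counts without that library, while extracellular matrix genes went from 20 to 13.

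**Figure D5:**
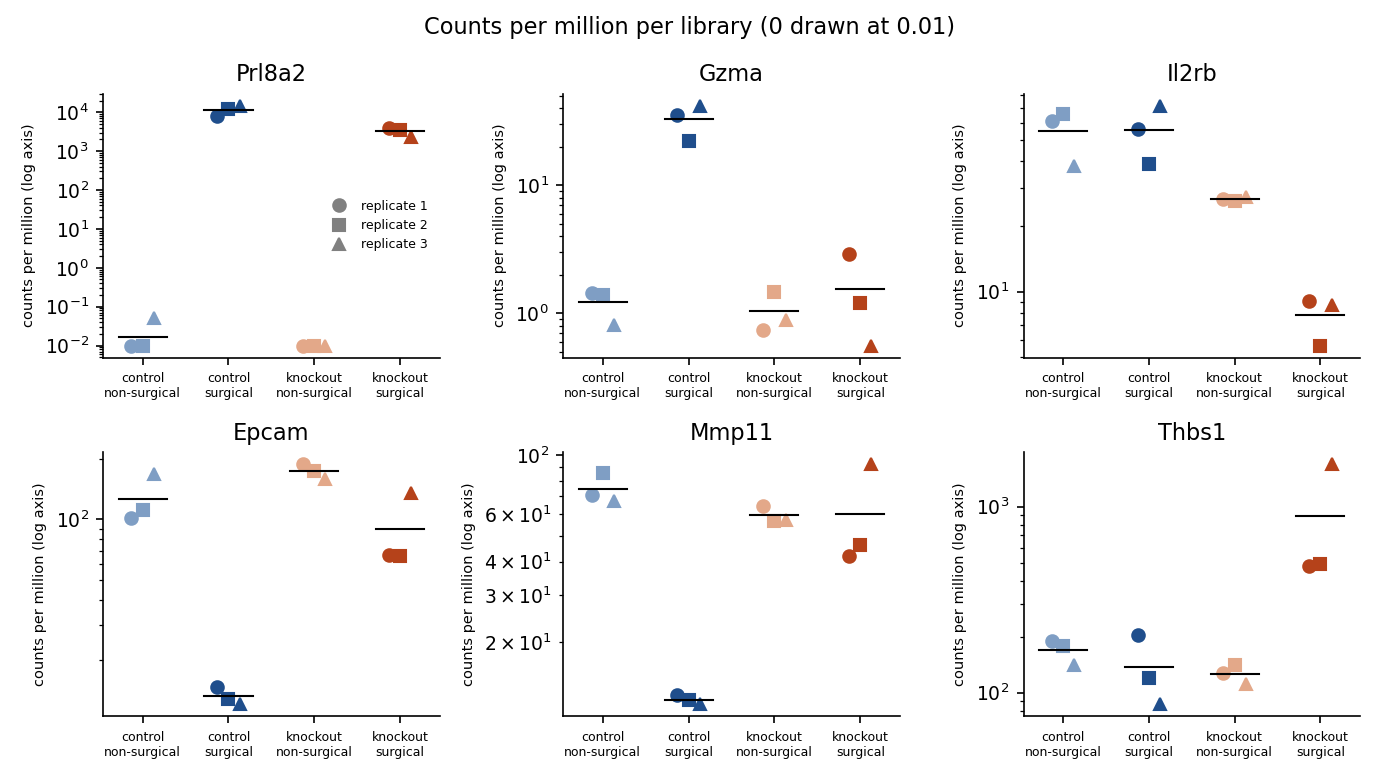
Levels in CPM on a log axis (vertical) of Prl8a2, Gzma, Il2rb, Epcam, Mmp11 and Thbs1 in each of the 12 libraries by group (horizontal), with lines for group means (n = 3). Il2rb averaged 55.7 in the control and 7.81 in the knockout surgical libraries.

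The comparison of knockout with control in the non-surgical horn addresses the genotype difference where no decidualization was induced. Tac2 (ENSMUSG00000025400), which encodes the neuropeptide neurokinin B, fell from 8.34 ± 1.03 to 1.55 ± 0.659 CPM in the knockout (-2.43 ± 0.25, adjusted p = 0.00592), with all 3 knockout below all 3 control libraries. It was the 1 gene of 18286 that passed the edgeR test, while 1601 genes had an unadjusted p under 0.05. With only the 6 libraries compared Tac2 did not pass (-2.43, adjusted p = 0.0815), and the 3 genes that passed were other genes, all higher in the knockout. The DESeq2 test called 112 genes and limma-voom 14. Without knockout surgical replicate 3, which adds to the estimate of the spread, edgeR called 25 genes, without control non-surgical replicate 1 it called 3, and without control non-surgical replicate 2, knockout non-surgical replicate 3 or knockout surgical replicate 1 it called 2.

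No member of any list passed over all genes in the non-surgical horn, and the lists below shifted by camera as sets. The median of 25 cell cycle genes was 0.82 (adjusted p = 2.81e-11, adjusted p = 0.496 with an estimated correlation), and 15 rose adjusted over the list alone. Mki67 was at 0.91 ± 0.21 (adjusted p = 0.271) and the mitotic checkpoint gene Bub1 at 1.21 ± 0.30 (adjusted p = 0.308). The median of 19 luminal epithelium markers was 0.53 (adjusted p = 1.62e-08, adjusted p = 0.487 with an estimated correlation), with 2 higher adjusted over the list alone. Wnt7a was at 1.81 ± 0.30 (adjusted p = 0.141) and Krt19 at 0.94 ± 0.20 (adjusted p = 0.261), which passed without knockout surgical replicate 3 (0.93, adjusted p = 0.0369). The medians of 16 estrogen-responsive genes (0.34, adjusted p = 0.00262, adjusted p = 0.487 with an estimated correlation), 77 ribosomal protein genes (0.13, adjusted p = 5.52e-08, adjusted p = 0.567 with an estimated correlation) and 13 mitochondrially encoded genes (0.23, adjusted p = 0.0182, adjusted p = 0.567 with an estimated correlation) were above 0. Within these lists Fgf18 was at 1.75 ± 0.50, Ltf at 1.65 ± 0.57 and Rps28 at 0.63 ± 0.17, none of which passed.

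Lists with a camera call toward lower levels in the non-surgical horn included 19 uterine natural killer cell markers (median -0.70, adjusted p = 8.47e-07, adjusted p = 0.487 with an estimated correlation), with 2 lower adjusted over the list alone. Il2rb was at -1.04 ± 0.24 (adjusted p = 0.276) and Klrb1c, a receptor gene of these cells, at -0.98 ± 0.29 (adjusted p = 0.390). The median of 15 macrophage markers was -0.69 (adjusted p = 2.09e-06, adjusted p = 0.496 with an estimated correlation), with Csf1r at -0.87 ± 0.25 and Cx3cr1 at -0.98 ± 0.31. For 5 red blood cell markers it was -0.97 (adjusted p = 0.00164, adjusted p = 0.496 with an estimated correlation), with 3 lower adjusted over the list alone and Hbb-bs at -1.25 ± 0.35. For 28 extracellular matrix genes it was -0.38 (adjusted p = 3.16e-05, adjusted p = 0.567 with an estimated correlation), with Col1a1 at -0.68 ± 0.24 and Lox at -0.82 ± 0.29. Matrix-degrading enzymes and inhibitors had a median of -0.29 (adjusted p = 0.00673, adjusted p = 0.567 with an estimated correlation), with Mmp7 at -2.25 ± 0.55, the 1 gene that was lower adjusted over the list alone. Focal adhesion and actin genes had a median of -0.14 (adjusted p = 0.00610, adjusted p = 0.567 with an estimated correlation).

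Smaller shifts in the non-surgical horn were those of 28 decidual stroma markers (median -0.09, adjusted p = 0.0428, adjusted p = 0.567 with an estimated correlation), with 2 lower adjusted over the list alone. In this list Fst, an activin-binding protein gene, was at -1.69 ± 0.32 (adjusted p = 0.176), Igfbp3 at -0.84 ± 0.22, Wnt4 at 0.82 ± 0.31, Hoxa10 at -0.26 ± 0.15, Hand2 at -0.08 ± 0.27 and Bmp2 at 0.04 ± 0.51; Bmp2 was below 0 without control non-surgical replicate 1 (-0.02) or knockout non-surgical replicate 1 (-0.01). Prl8a2 was at or under the floor of 3 counts in both groups. Progesterone signalling (median -0.21, adjusted p = 0.0259, adjusted p = 0.487 with an estimated correlation; 1 higher adjusted over the list alone), immediate early genes (-0.28, adjusted p = 0.0259, adjusted p = 0.663 with an estimated correlation), endoplasmic reticulum stress genes (-0.13, adjusted p = 0.0167, adjusted p = 0.567 with an estimated correlation), YAP and TAZ target genes (-0.13, adjusted p = 0.0362, adjusted p = 0.518 with an estimated correlation) and cholesterol and steroid synthesis genes (-0.15, adjusted p = 0.0402, adjusted p = 0.496 with an estimated correlation) were also shifted. Each list of this paragraph, and the estrogen-responsive, mitochondrially encoded and matrix-degrading lists, lost its call when at least 1 library was left out, with the highest adjusted p between 0.0675 and 0.281. No list passed fry in this comparison.

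The difference of the horn effect between genotypes asks which genes responded differently to induction in the knockout. Positive values mean a higher surgical minus non-surgical log2 change in the knockout. For genes that fell in both genotypes, a positive value is a smaller fall in the knockout. Pdzk1ip1, a membrane protein gene, went from 52.4 ± 15.1 to 159 ± 41.8 CPM between the horns in control and from 110 ± 27.1 to 12.6 ± 3.77 CPM in knockout mice (-4.73 ± 0.41, adjusted p = 4.08e-04). The metallothionein gene Mt1 (-2.81 ± 0.32, adjusted p = 0.00236), Wnt5a (-1.53 ± 0.19, adjusted p = 0.00373) and Sphk1, which makes sphingosine 1-phosphate (-3.00 ± 0.42, adjusted p = 0.00587), also had lower responses in the knockout. Rnase4, a secreted ribonuclease gene, went from 214 ± 22.7 to 292 ± 46.7 CPM in control and from 162 ± 43.1 to 1004 ± 109 CPM in knockout mice (2.19 ± 0.27, adjusted p = 0.00373). Gli2, a transcription factor of hedgehog signalling (1.87 ± 0.21, adjusted p = 0.00236), Plce1, a phospholipase gene (2.31 ± 0.26, adjusted p = 0.00236), and Mmp11 (2.62 ± 0.34, adjusted p = 0.00444) had higher responses.

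Responses of extracellular matrix genes were higher in the knockout for 15 of 28 genes (22 adjusted over the list alone; adjusted p = 3.25e-11, adjusted p = 0.441 with an estimated correlation), with Lox at 2.29 ± 0.41 and Loxl1 at 2.46 ± 0.48. They were higher for 10 of 21 matrix-degrading enzymes and inhibitors (13 adjusted over the list alone; adjusted p = 1.42e-06, adjusted p = 0.441 with an estimated correlation). Mmp2 was at 2.18 ± 0.35. For luminal epithelium markers 10 of 19 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 6.64e-05, adjusted p = 0.441 with an estimated correlation). Epcam was at 2.29 ± 0.37. The median change of this list between horns was -3.25 in control and -1.49 in knockout mice, a smaller fall. Smooth muscle markers were higher in 7 of 17 cases (15 adjusted over the list alone; adjusted p = 7.56e-08, adjusted p = 0.441 with an estimated correlation). Oxtr was at 4.84 ± 0.95 (3.26 without knockout surgical replicate 3). The smooth muscle median between horns was -1.59 in control and -0.11 in knockout mice, also a smaller fall. Macrophage markers were higher in 8 of 15 cases (12 adjusted over the list alone; adjusted p = 7.44e-06, adjusted p = 0.441 with an estimated correlation). Lyz2 was at 1.78 ± 0.37. Uterine natural killer cell markers were lower in 8 of 19 cases (11 lower and 1 higher adjusted over the list alone; adjusted p = 1.26e-05, adjusted p = 0.441 with an estimated correlation), with Il15ra at -1.53 ± 0.22 and Il2rb at -1.79 ± 0.35. Of 28 decidual stroma markers 1 was higher and 1 lower, with no camera call (adjusted p = 0.779) and a median of -0.05 that turned to 0.11 with total counts only. None of 8 prolactin-family genes passed, but 7 of them had no counts in at least 1 non-surgical group. Their horn changes rest on few reads there, so this does not show an equal response.

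YAP and TAZ target genes had higher responses in 10 of 23 cases (11 adjusted over the list alone; adjusted p = 0.00272, adjusted p = 0.441 with an estimated correlation). Axl was at 1.36 ± 0.26. Calcium signalling genes did in 4 of 28 cases (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.00272, adjusted p = 0.441 with an estimated correlation), with Rcan2 at 2.93 ± 0.40 and the calcium pump gene Atp2a2 at 0.73 ± 0.15. For focal adhesion and actin genes 2 of 24 were higher (5 adjusted over the list alone; adjusted p = 1.18e-04, adjusted p = 0.441 with an estimated correlation), and with offsets for GC content and transcript length 0 were higher and 1 lower. For immediate early genes 2 of 15 were higher (5 adjusted over the list alone; adjusted p = 0.00361, adjusted p = 0.498 with an estimated correlation). Nr4a1 was at 2.73 ± 0.54 (1.91 without knockout surgical replicate 3). Cell cycle genes were lower in 2 of 25 cases (6 adjusted over the list alone; adjusted p = 5.00e-08, adjusted p = 0.442 with an estimated correlation). Between genotypes the median of this list was 0.82 in the non-surgical horn and -0.17 in the surgical horn. Without knockout surgical replicate 3 the surgical value was 0.09. The lower response thus rests mainly on higher levels in the knockout non-surgical horn. The mitotic kinase gene Bub1 was at -1.28 ± 0.39 (adjusted p = 0.0600). The median of 77 ribosomal protein genes was -0.30 with none passing (adjusted p = 3.77e-09, adjusted p = 0.481 with an estimated correlation).

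The camera calls of 6 further lists in this comparison ended when 1 library was left out. The libraries were control non-surgical replicates 1, 2 and 3, control surgical replicates 1 and 3, knockout non-surgical replicates 1 and 2 and knockout surgical replicate 3. The lists were BMP and TGF-beta genes (6 of 26 higher and 1 lower, 11 and 5 adjusted over the list alone; adjusted p = 0.0263, adjusted p = 0.441 with an estimated correlation), with Tgfb3 at 1.18 ± 0.22, and neutrophil markers (3 of 8 higher, 6 adjusted over the list alone; adjusted p = 0.0242, adjusted p = 0.442 with an estimated correlation). Mechanosensitive ion channel genes were higher in 2 of 16 cases (6 adjusted over the list alone; adjusted p = 0.0397, adjusted p = 0.441 with an estimated correlation), and inflammatory cytokines and chemokines in 2 of 15 (5 adjusted over the list alone; adjusted p = 0.0143, adjusted p = 0.498 with an estimated correlation). Of 21 glycolysis and hypoxia genes 1 was higher (0 adjusted over the list alone, and 0 with offsets for GC content and transcript length, where the median went from 0.41 to 0.17; adjusted p = 0.0490, adjusted p = 0.598 with an estimated correlation). None of 13 mitochondrially encoded genes passed (median -0.37, adjusted p = 0.0182, adjusted p = 0.481 with an estimated correlation). The highest adjusted p of these 6 lists with 1 library left out lay between 0.0614 and 0.109. Among lists without a camera call, Wnt pathway genes were higher in 4 of 27 cases and lower in 3 (6 and 3 adjusted over the list alone). Nkd2 was at 2.20 ± 0.30. Estrogen-responsive genes were higher in 5 of 16 cases and lower in 1 (6 and 2 adjusted over the list alone), with the complement gene C3 at 2.99 ± 0.57, and angiogenic factors were higher in 4 of 16 (5 higher and 1 lower adjusted over the list alone). Without knockout surgical replicate 3 the higher and lower counts were 6 and 3 for BMP and TGF-beta genes, 4 and 1 for calcium signalling, 0 and 1 for cell cycle, 2 and 3 for decidual stroma, 3 and 0 for glycolysis and hypoxia and 1 and 0 for mechanosensitive ion channel genes.

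By the edgeR test 1623 genes passed the interaction, 1122 with a higher and 501 with a lower response in the knockout. In the 9 regroupings that kept the genotype labels of the surgical libraries and mixed or exchanged the non-surgical ones, 843 to 1614 passed. Over 14502 genes the horn effects of the genotypes correlated across genes, which are not independent replicates (Pearson r = 0.881, Spearman rho = 0.832), with a total least squares slope of knockout on control of 0.815, and 0.849 without knockout surgical replicate 3. Of the genes tested, 4270 rose in both genotypes and 4084 fell in both, while 37 rose in control and fell in knockout mice and 87 did the reverse. Counts of the interaction were 572 without control surgical replicate 3, 646 without control surgical replicate 2, 678, 938 and 946 without control non-surgical replicates 2, 1 and 3, and 811 and 964 without knockout non-surgical replicates 1 and 3. With total counts only 1535 were higher and 363 lower, and with offsets for GC content and transcript length 932 and 852.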

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

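All tests of explanations in this part were chosen only after the results were seen, with their limits. A test of the difference between genotypes singled out the horn effects below.

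In the interaction 1623 genes passed. With positive values for a higher surgical minus non-surgical change in the knockout, the named genes were Ang (1.76), Gli2 (1.87), Plce1 (2.31), Rnase4 (2.19), Nmur2 (5.53), Slitrk3 (3.08), Slc28a3 (4.72), Mmp11 (2.62), Gxylt2 (1.55), Hpgd (1.55), Pdzk1ip1 (-4.73), Vipr1 (-2.82), Adrb2 (-2.17), Mt1 (-2.81), Minar1 (-4.93), Wnt5a (-1.53), Tspo (-1.06), Fam210b (-1.90), Sphk1 (-3.00) and Psat1 (-1.15). Camera gave adjusted p-values of 6.64e-05 for luminal epithelium markers, 7.56e-08 for smooth muscle markers, 1.26e-05 for uterine natural killer cell markers, 7.44e-06 for macrophage markers, 0.0242 for neutrophil markers, 5.00e-08 for cell cycle genes, 3.25e-11 for extracellular matrix genes, 1.42e-06 for matrix-degrading enzymes and inhibitors, 0.00272 for YAP and TAZ target genes and 0.0397 for mechanosensitive ion channels. It gave 0.00272 for calcium signalling genes, 1.18e-04 for focal adhesion and actin genes, 0.0263 for BMP and TGF-beta genes, 0.00361 for immediate early genes, 0.0490 for glycolysis and hypoxia genes, 0.0143 for inflammatory cytokines and chemokines, 0.0182 for mitochondrially encoded genes and 3.77e-09 for ribosomal protein genes. Nmur2 was at 4.83 without knockout surgical replicate 3. The fitted value of Slc28a3 rests on 2 counts in the control surgical libraries, which were 194.8-fold lower than the control non-surgical ones (95% counting interval 53.68 to 1613) and 44.16-fold lower than the knockout surgical ones (11.86 to 370.5). With an estimated correlation the adjusted p of these 18 lists lay between 0.441 and 0.598.

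For the interaction, the splits do not decide on chance: 1 of 100 splits, the real 1, gave as many as 1623 genes, and the highest of the others gave 1614. That split was 1 of 9 that kept the genotype labels of the surgical libraries, which gave 843 to 1614 genes, while the highest of the splits that did not keep them gave 1. The count therefore follows the genotype labels of the surgical libraries, and the splits repeat that comparison rather than test the interaction itself. For the comparisons of 3 against 3 libraries, the 10 splits are too few to decide: the real values were 11666 and 10528 genes between horns in control and knockout mice, 3966 between genotypes in the surgical horn and 1 in the non-surgical horn, and the highest other split of each gave 0.

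The genotype difference in the surgical horn may in part reflect a share of tissue like the non-surgical horn in the knockout surgical libraries. Such a mixture lies between its sources. Yet 702 of the 2470 genes that rose were above both the control surgical libraries and the mean of the non-surgical groups of both genotypes. That is 28.4%, and 26.0% without knockout surgical replicate 3, which argues against a mixture as the whole cause for these genes. This was compared with TMM scaling only, and a gene higher in the knockout non-surgical group could pass and still be a mixture. The mixture would also lower all genes nearly absent from the non-surgical horn by 1 ratio. Their changes differed by more than their errors (Q = 917 over 108 genes, SD 1.23 against a median SE of 0.42). For the 959 genes that rose and stayed below the non-surgical libraries the mixture cannot be told apart from a weaker response. Both place these genes between the horns. By list, 3 of 17 luminal epithelium and 3 of 16 smooth muscle markers that rose were above both, and 0 of 3 glandular markers. Of 20 extracellular matrix genes that rose, 16 were. A share of such tissue thus stays open for most of the epithelial and smooth muscle rises. Of 1496 genes that fell, 278 (18.6%) were below both, as were 6 of the 14 natural killer cell markers that fell. A mixture alone would not place a gene there, unless the gene was also lower in the knockout than in the control non-surgical group. By median the natural killer cell list was (-0.70). Offsets for GC content and transcript length kept 89.9% of the calls in the same direction, which argues against these as the whole cause, although the balance of higher and lower genes turned, to 2096 and 2702, and a response that differs by genotype stays open. The interaction, in which 1623 genes passed, tests for such a response, but a share of tissue would also give an interaction.

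The library labelled knockout surgical replicate 3 stood apart from its group. A swap with a control surgical library would exchange the places of both. On genotype genes called without both libraries, control surgical replicates 1, 2 and 3 lay nearer to the other knockout libraries at 25.4%, 6.26% and 4.13% of the genes. The library in question did so at 92.3%, 93.1% and 94.6%. This excludes a swap only between libraries that resemble their true groups at these genes. The library itself lay nearer to the other knockout libraries at 92.8% of the 2401 genotype genes called without it. This excludes a control like the other 3 under a wrong label, while a control unlike them or a sample from outside these groups stays open. At 80.4% of these genes it lay beyond the mean of the other knockout libraries. Its median position was 1.57, with the control mean at 0 and that mean at 1. Of 134 genes named and called in the surgical horn, 25 lost their call without it, where the group also had fewer libraries. Piezo1 reads in a knockout library could come from exons that a deletion leaves in place, and counts over the whole gene keep this open. Such exons would be present in every knockout library. They would not by themselves place knockout surgical replicate 3, at 62.2 CPM, above replicates 1 and 2, at 31.8 and 28.6 CPM. The cause of that difference was not tested.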

How the results depend on the processing

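The alternatives for scaling, filter, test, threshold, libraries and block were chosen before the data were examined, and the offsets for GC content and transcript length after. Over all of these the counts of the horn comparisons stayed within 1.5 times except with a 2-fold minimum (7266 in control, 6063 in knockout mice). Of the genes named and called, 151 of 161 in control and 143 of 152 in knockout mice kept their call in every setting, as did 79 of 134 in the surgical horn and 51 of 90 in the interaction. For the values below the cause was not tested, beyond fewer genes or libraries where the setting names them.

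Between genotypes in the surgical horn the count was 2111 with a 2-fold minimum, 1705 at an adjusted p under 0.01, 1984 with only the 6 libraries compared, and 2187 to 4246 with 1 library left out. In the non-surgical horn it was 112 with the DESeq2 test, 14 with limma-voom, 64 with no filter, 3 with only the 6 libraries (Tac2, the 1 gene called with all libraries, not among them) and 1 to 25 with 1 library left out. In the interaction it was 211 at an adjusted p under 0.01, 2716 with the DESeq2 test and 572 to 2229 with 1 library left out. With replicate numbers as a block the counts were 11113, 9853, 3423, 2 and 1297. The block was genotype with number for the horn comparisons and the interaction, and number alone for the genotype comparisons. Same-number correlations lay from -0.03 to 0.13 between horns of the same genotype and from -0.30 to 0.12 between genotypes. They showed no pairing by number, but 3 libraries per group are too few to exclude it.

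With total counts only, Piezo1 between horns was at -1.01 in control and -0.0274 in knockout mice, Hoxa10 at -0.17, mt-Nd2 at -0.22, mt-Cytb at -0.13 and mt-Nd1 at -0.17 between horns in control mice, and Hoxa10 at 0.0696 between genotypes in the surgical horn. With no filter Piezo1 was at -1.07 in the non-surgical horn. With 1 library left out, Piezo1 ranged from -0.0385 to 0.60 between horns in knockout mice and from -0.60 to 0.0327 between genotypes in the surgical horn. Wnt4 ranged from -0.40 to 0.11 and Hoxa10 from -0.13 to 0.0864 there, Bmp2 from -0.0202 to 0.13 in the non-surgical horn, and Cfd from -9.87 to 2.01 between horns in control mice, as fitted on 1 count in the surgical horn (312.2-fold lower, 95% counting interval 55.74 to 12360).

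Camera called 13 lists between horns in control and 19 in knockout mice, 22 between genotypes in the surgical and 18 in the non-surgical horn, and 18 in the interaction. With an estimated correlation 0 lists passed in each of the 5 comparisons, and with fry 22 passed between horns in control and 27 in knockout mice, 13 between genotypes in the surgical horn, 0 in the non-surgical horn and 4 in the interaction. Depth limits genes near the floor of 3 counts, whose ratios rest on few reads. The alternative for FPKM values was not run.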

Other observations

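Mast cell and eosinophil markers held genes that moved apart in the surgical horn of the knockout: 3 of 8 fell and 1 rose (3 and 0 without knockout surgical replicate 3). Kit, a receptor gene of mast cells and other cell types, went from 90.2 to 31.8 CPM (-1.50 ± 0.25, adjusted p = 0.00189), and the tryptase gene Tpsb2 from 67.5 to 8.37 CPM (-3.01 ± 0.73, adjusted p = 0.0122, and -3.94 without knockout surgical replicate 2). In control mice both rose in the surgical horn, Kit by 2.04 ± 0.25 and Tpsb2 by 3.93 ± 0.76. T and B cell markers fell in the surgical horn for 7 of 10 genes in control and 3 of 10 in knockout mice (1 adjusted over the list alone), and 1 of 10 was higher in the knockout surgical horn.

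Oviduct and ovary markers fell in the surgical horn for 6 of 8 genes in control mice and 4 of 8 in knockout mice, and 1 rose in each, with the cilia gene Ccdc39 at -2.15 ± 0.21 and -1.80 ± 0.21. Of 5 neural and Schwann cell markers, the ubiquitin hydrolase gene Uchl1 rose in both (3.28 ± 0.25 and 3.31 ± 0.25) and the myelin gene Plp1 fell in both (-1.82 ± 0.25 and -1.89 ± 0.25). Of 8 adipocyte markers 2 rose and 3 fell in control mice, and 1 rose and 2 fell in knockout mice (0 and 2 adjusted over the list alone). Mesothelium markers were higher in the knockout surgical horn for 4 of 7 genes, and for 0 without knockout surgical replicate 3. In the non-surgical horn their camera test gave an adjusted p of 4.59e-04 (adjusted p = 0.487 with an estimated correlation), and 0.0520 without control non-surgical replicate 1. Camera called none of the other lists of this part in any comparison.

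A hypothesis formed after the values were seen, tested on the same data, was that the knockout surgical horn may hold a lower share of natural killer cells and nothing else changed in these cells. A lower share alone would lower by 1 ratio the markers that no other cells express. Over 17 markers, the list without Il15 and Il15ra, the changes differed by more than their errors (Q = 204 on 16 degrees of freedom, weighted mean -2.17). Those of the 8 granule genes did not (Q = 8.57 on 7 degrees of freedom). The granule genes averaged -3.65 (SD 0.53) and the 9 other markers -1.40 (SD 1.38; exact permutation p = 2.47e-04 over genes, which are not independent), and other cell types in the uterus also express some of these markers, which would give unequal falls. Reads shared between near-identical granzyme genes would also make the granule ratios alike, so their low Q is weak evidence for 1 ratio. A lower share alone, and a lower share together with lower granule gene levels per cell, therefore both stay open.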
